A study of Mus musculus with 8 samples.

How the data were processed

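RNA was sequenced from tdTomato-positive cells sorted from hind limb muscle of adult C57BL/6 mice carrying a tamoxifen-inducible Cre recombinase at Pax7 or Twist2 (Tw2), after 3 tamoxifen treatments given 10 days before harvest. Per the labels, the sorted cells grew on Matrigel, with a growth medium of Ham's F10 and 20% fetal bovine serum, and a second medium with 2% horse serum and bFGF was used for differentiation. Total RNA was taken with Trizol and chloroform, and libraries were made by an Illumina protocol whose strand handling is not stated. The 8 libraries were grouped by their titles into Pax7_GM, Pax7_48, Tw2_GM and Tw2_48, with 2 libraries each. The submitters' processing notes name TopHat2 2.0.0, DESeq2 1.6.3 and the GRCm38 (mm10) genome without saying what each was used for, and name neither a counting tool nor an annotation.

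The authors deposited 1 table of 5457 genes with the mean CPM (reads scaled to library size) of each group and 3 log2 fold changes against Tw2_GM. Recomputed as log2 of (group mean + 1) over (Tw2_GM mean + 1), the deposited log2 fold changes were matched to within 1.4e-11. A further column, status, holds 1 for every gene. Every listed gene had an absolute deposited log2 fold change of at least 1 in at least 1 of the 3 comparisons, and every gene solved below was at 10 CPM or more in at least 4 of the 8 libraries. The table is therefore selected on the size of the difference from Tw2_GM, genes outside it were not analysed here, and all tests and enrichments are relative to the listed genes.

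Each deposited mean CPM was taken apart into its 2 libraries. A mean of 2 libraries' CPM is a whole number of reads times 1 step plus a whole number times another, and the steps give each library's implied size. For each gene and group, all pairs of whole read counts that gave the deposited mean to within 1.1 times its rounding error were counted, with no regard to how alike the 2 libraries were. For 5451 genes all 4 groups had a single solution. The other 6 (Myh3, Cfl2, Actc1, Mylpf, H19 and Acta1) were left out of the tests. On simulated means the solver found 5453 to 5457 of 5457 genes, all with the right reads. The median absolute log2 ratio of the 2 libraries was 0.11 (Pax7_48, Tw2_GM), 0.12 (Tw2_48) and 0.33 (Pax7_GM), against 1.47 if each mean were split at random. The 2 libraries of a group are called deeper and shallower, since the means do not carry replicate numbers.

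The implied library sizes ranged from 5.18 to 13.7 M reads and the reads in listed genes from 2.30 to 9.90 M. At these depths 3 reads, the upper 95% limit of a count of 0, come to 0.246 and 0.266 CPM in Tw2_GM, 0.406 and 0.579 CPM in Pax7_GM, 0.218 and 0.319 CPM in Tw2_48, and 0.282 and 0.393 CPM in Pax7_48. These limits cover counting error alone. The spread of the 2 libraries over that of counting (chi-square per degree of freedom) was 3.9 in Pax7_48, 6.3 in Tw2_48, 8.9 in Tw2_GM and 21.1 in Pax7_GM.

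Before the data were examined, the comparisons, the tests, the 27 gene lists, the rule for naming genes and the first set of alternatives were fixed. Because the unit is CPM, limma 3.58.1 (R 4.3.3) was used on log2(CPM + 1) with 1 mean per group over all 8 libraries, eBayes without trend (4 residual degrees of freedom, prior degrees of freedom 4.0, prior SD 0.16) and Benjamini-Hochberg adjustment over the 5451 genes within a comparison. The comparisons were Tw2 against Pax7 in GM, at 48 and as the mean of both, 48 against GM in each lineage, and the difference of those changes between the lineages. A gene was called at adjusted p under 0.05. The pseudocount of 1 makes the log2 change of genes near 1 CPM smaller than the change in CPM itself. A filter at a mean of 1 CPM removed no gene. Median standard errors were 0.16 within a culture or lineage, 0.12 over both cultures and 0.23 for the difference of changes.

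Named genes are Pax7 in every comparison, and then the 10 largest positive and negative log2 fold changes of each lineage comparison, and the 5 of the others, among called genes whose libraries do not overlap between the groups, without predicted gene models. Up to 4 of the called members with the largest change may be named from each list. Some genes that these rules give are not reported here. Twist2, Twist1 and Pax3 are not among the genes analysed here. Genes named only with values from the authors' deposited table are those that were not solved.

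The lists cover the sort genes, satellite cells and Notch, myogenic commitment and fusion, sarcomere and calcium handling, fibro-adipogenic progenitors, collagens, elastic fibre and matricellular proteins, basement membrane, matrix proteases, cell cycle, axon guidance, cytokines, interferon-stimulated genes, Tgf-beta and Bmp, Wnt, Hox and limb identity, and dissociation and immediate early genes. They also cover endothelium, pericytes, immune cells, adipocytes, tenocytes, glia, bone and cartilage, oxidative phosphorylation, mitochondrially encoded genes and sex-linked genes. No member of the mitochondrially encoded list was among the genes tested, 1 sort gene (Pax7) was, and 8 lists with fewer than 5 tested members were only counted. The other 19 were tested with limma camera at a preset correlation of 0.01, adjusted over lists within a comparison, with the estimated correlation and fry beside it. No list was called in any comparison with the estimated correlation. Counts of members use the adjusted p over all genes, with those adjusted over the list alone beside them.

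That first set was size factors (median of ratios over the listed genes), quantile normalization, limma with an intensity trend, no filter, a filter at 10 CPM, and pseudocounts of 0.1 and 10. Both scalings presume that levels are largely alike across libraries, which need not hold for genes selected for a difference. The first set also held only the compared groups, each library left out in turn, and a further minimum of 1 on the absolute log2 fold change. Alternatives chosen after seeing the data were removal of a GC and length trend, counting the protein-coding genes of GENCODE vM21 that are not listed as tests with p of 1, a separate spread per group, and the list tests under scaling, trend removal and left-out libraries. For the trend, the GC content and length of each gene's longest annotated transcript came from GENCODE vM21 for 5246 genes (96.2% of those tested). In each library, each gene's deviation from its mean over the libraries was regressed on natural splines with 5 degrees of freedom of GC content and of log2 length. The fit, less its mean over the genes of that library, was subtracted. Each library's mean level was thus kept, and a difference in level between libraries over all genes was not removed. Coordinates are from the same annotation.

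For each simulation, counts were drawn with 1 spread per group and no trend with GC content, and 200 genes were changed by 1.5, 2 or 4-fold. Confidence intervals of list medians came from 10000 bootstrap resamples of genes and cover neither library spread nor selection. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for solving and figures.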

Results

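Cells were sorted from the hind limb muscle of adult C57BL/6 mice in which Cre recombinase, expressed from Pax7 or from Twist2 (Tw2) and induced by tamoxifen, had switched on the red fluorescent protein tdTomato. Pax7 encodes the transcription factor that marks satellite cells, the resident stem cells of muscle, and Twist2 encodes a basic helix-loop-helix transcription factor. RNA was sequenced from 8 libraries in 4 groups of 2. Pax7_GM and Tw2_GM came from cells titled GM (growth medium), and Pax7_48 and Tw2_48 from cultures titled 48. The labels do not state what 48 counts in the Pax7 titles (the Tw2 titles give it in hours) or which medium those cultures were in. The values cover 5457 genes, each at least 2-fold different from Tw2_GM in at least 1 other group by the authors' means, so every share below is a share of genes selected for such a difference.

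Implied library sizes were 12.2 and 11.3 M reads in Tw2_GM, 7.38 and 5.18 M in Pax7_GM, 13.7 and 9.40 M in Tw2_48, and 10.6 and 7.64 M in Pax7_48. The listed genes held 60.5 and 59.5% of the reads of Tw2_GM, 45.8 and 44.4% of Pax7_GM, 72.1 and 69.4% of Tw2_48, and 58.3 and 58.8% of Pax7_48. The 2 libraries of a group correlated at 0.994 (Tw2_GM), 0.996 (Tw2_48) and 0.995 (Pax7_48), and at 0.962 in Pax7_GM, where the SD of their log2 ratio was 0.50 against 0.17 to 0.20 in the other groups. P-values below measure only the spread between these libraries, since the labels do not say that they came from separate mice or cultures. For each gene that spread was pooled over all groups. The standard error of a comparison of 2 groups thus also reflects libraries outside that comparison, and is not the spread of the compared libraries alone.

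In growth medium, genes of the contractile apparatus were lower in Tw2 cells than in Pax7 cells, while the direction of Pax7 itself depended on the processing. Mb, which encodes myoglobin, the oxygen-binding protein of muscle, stood at 6.08 and 4.25 CPM (reads scaled to library size) in the Tw2_GM libraries and at 233 and 166 CPM in Pax7_GM. Its log2 fold change was −5.02 ± 0.21 (standard error, SE; 2 libraries per group; limma adjusted p = 4.25e-06). Also lower were Casq1 (−4.10 ± 0.13), the calcium-binding protein of the sarcoplasmic reticulum, and Myl4 (−4.01 ± 0.18), a myosin light chain. Actn2 (−3.95 ± 0.19), the alpha-actinin of the Z-disc, and Tcap (−3.59 ± 0.18), a titin-binding protein there, were lower too. The adjusted p of these 4 ran from 3.64e-06 to 6.31e-06. Pax7 was at 113 and 109 CPM in Tw2_GM and at 117 and 112 CPM in Pax7_GM, with a log2 fold change of −0.05 ± 0.12 (adjusted p = 0.738). That value was −0.91 with size factors and −0.60 with quantile normalization, and 0.50 (adjusted p = 0.00238) once a trend with transcript GC content and length, described below, was removed. It was called under each of these 3. Both scalings used the listed genes alone, of which 1821 were at least 2-fold lower in Pax7_GM than in Tw2_GM and 527 higher. That selection can thus enter the 2 scaled values. Removal of the trend kept each library's mean level, and the median of all genes was 0.53 with it removed. Mb was at −3.75 with the trend removed, Casq1 at −3.16 and Tcap at −2.33.

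The largest difference of all was that of Col1a2 (chromosome 6, 4504814 to 4541544), a chain of type I collagen, at 3.61 and 3.28 CPM in Tw2_GM and 424 and 387 CPM in Pax7_GM (log2 fold change −6.51 ± 0.44, adjusted p = 1.91e-05). Syt13, a member of the synaptotagmin family, was at −4.24 ± 0.18, Arhgef5, a nucleotide exchange factor, at −4.06 ± 0.14, the actin-binding LIM protein Ablim3 at −3.94 ± 0.17 and Igfn1 at −3.83 ± 0.15. In the authors' deposited table, the means of Acta1, the skeletal muscle actin, were 180 CPM in Tw2_GM and 1223 CPM in Pax7_GM. Those of Mylpf, a fast myosin light chain, were 90.1 and 968 CPM in the authors' deposited table, and those of the embryonic myosin heavy chain Myh3 were 91.1 and 388 CPM.

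Dynap was the gene highest in Tw2 over Pax7 cells, at 378 and 465 CPM against 10.6 and 11.8 CPM (log2 fold change 5.11 ± 0.17, adjusted p = 3.64e-06). Piezo2, a mechanically gated ion channel, was at 184 and 148 CPM in Tw2_GM against 10.0 and 10.2 CPM (3.90 ± 0.21, adjusted p = 6.93e-06). Ptgs2, an enzyme of prostaglandin synthesis, was at 350 and 369 CPM against 23.0 and 32.2 CPM (3.67 ± 0.17, adjusted p = 4.94e-06). Selp, which encodes the adhesion molecule P-selectin, reached 584 and 793 CPM against 56.9 and 60.2 CPM (3.52 ± 0.22). Higher in Tw2_GM as well were Flrt2 (3.85 ± 0.21), a transmembrane guidance protein, Dock11 (3.84 ± 0.31), an exchange factor for Cdc42, and Pik3c2a (3.62 ± 0.49), a phosphoinositide kinase. So were Far1 (3.60 ± 0.47), an enzyme of ether lipid synthesis, the RNA-binding protein Fmr1 (3.54 ± 0.38) and the nuclear import receptor Ipo7 (3.44 ± 0.34). With the GC and length trend removed, the log2 fold changes of Flrt2, Dock11 and Ptgs2 were smaller (2.47, 2.46 and 2.33), as were those of Pik3c2a, Far1, Fmr1 and Ipo7 (1.92, 1.96, 2.13 and 2.09). Those of Dynap, Piezo2 and Selp were 4.92, 3.90 and 4.12.

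**Figure D1:**
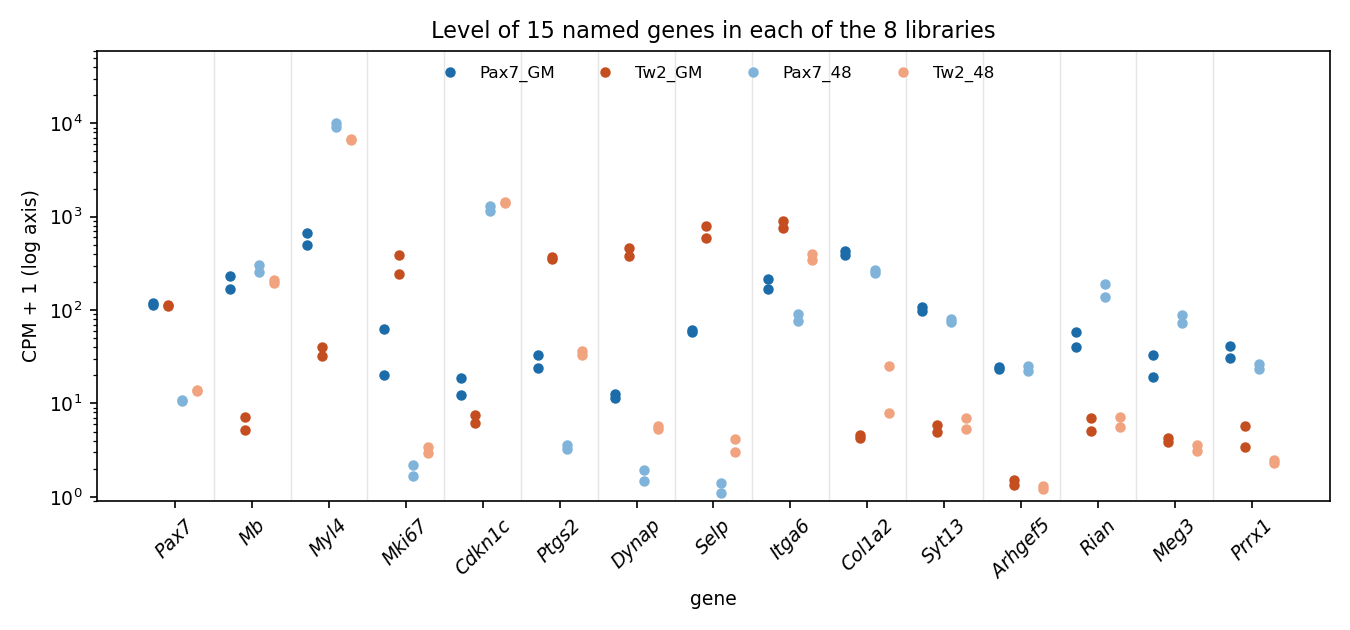
CPM of each library for 15 of the named genes. Mb was at 6.08 and 4.25 CPM in Tw2_GM and at 233 and 166 CPM in Pax7_GM, and Dynap at 378 and 465 CPM and at 10.6 and 11.8 CPM.

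Of 54 genes of the sarcomere and of calcium handling, 44 were lower in Tw2_GM, 2 were higher and the rest were not called, with a median log2 fold change of −1.81 and the same counts when p was adjusted over the list alone. The enrichment test gave adjusted p = 2.41e-18 for this list, and adjusted p = 0.308 with an estimated correlation. There were 37 lower and 8 higher with the trend removed. Of 32 genes of myogenic commitment and fusion, 19 were lower and 9 higher (again the same adjusted over the list alone). Lower were Gm7325 (−3.11 ± 0.21), the gene of the fusion protein myomixer, the transcription factor Mef2c (−2.57 ± 0.25), the myosin chaperone Unc45b (−2.57 ± 0.18) and caveolin 3, Cav3 (−2.39 ± 0.18), with Mef2c at −4.02 and Cav3 at −1.11 once the trend was removed. The median of this list was −0.80 (adjusted p = 0.000687, and adjusted p = 0.308 with an estimated correlation), and 0.06 with the trend removed, where 11 were lower and 11 higher. Nuclear genes of mitochondrial oxidative phosphorylation were lower in 25 of 30 members and higher in 1 (27 and 1 adjusted over the list alone), with a median of −0.55. With the trend removed the median was 0.45, with 4 lower and 21 higher. Its adjusted p = 2.82e-06 became adjusted p = 0.663 with an estimated correlation. The muscle forms of cytochrome c oxidase subunits led this list, Cox6a2 at −2.81 ± 0.18 and Cox8b at −2.17 ± 0.24 (−1.46 and −0.57 with the trend removed), while the complex I subunit Ndufs1 was higher at 1.24 ± 0.23, a call lost with size factors (0.37, adjusted p = 0.128).

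Of 45 cell cycle genes, 22 were higher in Tw2_GM and 3 lower (19 and 1 adjusted over the list alone), with a median of 0.37. That median became −0.49 with size factors, −0.14 with quantile normalization and 0.79 with the trend removed, where 36 were higher and 2 lower. The enrichment test gave adjusted p = 0.37, and adjusted p = 0.168 with the trend removed. Mki67, the proliferation marker, was at 386 and 243 CPM against 19.1 and 61.5 CPM (3.12 ± 0.47, adjusted p = 0.000494), and the topoisomerase Top2a was at 2.84 ± 0.33. Ect2 (2.41 ± 0.28) and Anln (2.23 ± 0.22), which act in cytokinesis, were also higher. Top2a was at 1.84 and Ect2 at 1.13 with the trend removed.

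Satellite cell and Notch genes went both ways, 7 higher and 6 lower of 25, with the paternally expressed Peg3 at 2.28 ± 0.24 and Spry1, an inhibitor of receptor tyrosine kinase signalling, at −1.78 ± 0.16. Among markers of fibro-adipogenic progenitors and fibroblasts, 4 of 14 were higher and 6 lower, with the transcription factor Prrx1 at −3.01 ± 0.25 and the hyaluronan synthase Has2 at 2.87 ± 0.35. Collagens and their processing had 6 higher and 4 lower of 17 (6 and 3 adjusted over the list alone), with Col8a1 at 2.09 ± 0.27 beside the low Col1a2. Elastic fibre and matricellular genes had 6 higher and 8 lower of 21, with the elastic fibre protein Emilin1 at −2.59 ± 0.20 and Ltbp2, a latent Tgf-beta binding protein, at −2.38 ± 0.14. Basement membrane genes had 9 higher and 4 lower of 17, with the laminin receptor subunit Itga6 at 2.10 ± 0.18 and Frem2 at −2.79 ± 0.15, and matrix proteases and inhibitors had 7 higher and 4 lower of 13. Axon guidance genes had 13 higher and 3 lower of 28 (12 and 3 adjusted over the list alone), led by the secreted cues Sema3a (2.94 ± 0.32) and Ntn1 (1.65 ± 0.13). In Tgf-beta and Bmp signalling 8 were higher and 6 lower of 24, with the receptors Bmpr1a (2.82 ± 0.32) and Tgfbr1 (2.82 ± 0.32) and the co-receptor Eng (2.59 ± 0.18) above the rest as deposited. Eng was at 3.43 with the trend removed, Bmpr1a at 1.46, Tgfbr1 at 1.44, Sema3a at 1.52, Has2 at 1.62 and Spry1 at −0.84. Wnt genes had 3 higher and 2 lower of 10, Hox and limb identity genes 2 and 2 of 9, and dissociation and immediate early genes 4 and 5 of 18 (4 and 3 adjusted over the list alone).

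These counts depended on the trend, and with it removed higher genes outnumbered lower ones in each of these lists. The same held for all genes, of which 3303 were higher and 784 lower with the trend removed. Each library's mean level was kept in that removal, and the median of all genes after it was 0.53. Against the other genes none of these lists was called with the trend removed (camera adjusted p from 0.229 to 0.978). There were then 16 higher and 6 lower satellite cell and Notch genes, 5 and 2 fibro-adipogenic markers, 11 and 1 collagen genes, and 10 and 5 matricellular genes (of 18 with GC content). Basement membrane genes were at 11 and 1, matrix proteases at 8 and 2, axon guidance genes at 22 and 5, and Tgf-beta and Bmp genes at 16 and 3. Wnt genes were at 6 and 2, Hox genes at 7 and 1, and immediate early genes at 14 and 0, with a median of 0.72 in place of −0.20.

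Markers of other cell types moved in both directions. Pericyte and smooth muscle markers had 2 higher and 4 lower of 10, adipocyte markers 1 and 4 of 5, and bone and cartilage markers 2 and 1 of 5. The carbonic anhydrase Car3 was at −2.72 ± 0.17 and the desaturase Scd1 at −2.16 ± 0.26. Glial and neural markers had 2 higher and 2 lower of 4, endothelial markers 1 and 1 of 3 (1 and 0 adjusted over the list alone), and tenocyte markers 0 and 1 of 3 (1 and 2 adjusted over the list alone). The only immune gene tested, Itgam, had 0 reads in both Tw2_GM libraries and 0.542 and 0.579 CPM in Pax7_GM. With the trend removed pericyte markers had 7 higher and 2 lower (median 0.57 in place of −0.28), adipocyte markers 2 and 3, bone markers 3 and 2, glial markers 3 and 1, and endothelial and tenocyte markers 2 and 1 each. Among inflammatory cytokines and chemokines 1 was higher and 3 lower of 6, and of 4 interferon-stimulated genes 2 were lower, including the class I antigen H2-K1 (−2.84 ± 0.13, and −1.76 with the trend removed). Removal of the trend gave 2 higher and 2 lower cytokines (median 0.17 in place of −0.24) and 1 higher and 1 lower interferon-stimulated gene. Xist, the RNA that coats the inactive X chromosome, was at 1188 and 659 CPM in Tw2_GM and at 45.9 and 175 CPM in Pax7_GM (3.29 ± 0.54, adjusted p = 0.000773, and 1.80 with the trend removed). The labels do not give the sex of the mice, so a difference in sex is not separated from lineage for Xist or for genes of the X chromosome such as Dock11 and Fmr1. Besides the sarcomere, commitment and oxidative phosphorylation lists, the other 16 of the 19 lists tested for enrichment were not called (adjusted p from 0.124 to 0.947), although the adipocyte list was with the trend removed (adjusted p = 0.0304, and adjusted p = 0.975 with an estimated correlation). Size factors changed the sign of the median in 9 of these 19 lists (collagens, matricellular, basement membrane, matrix proteases, cell cycle, axon guidance, Tgf-beta, Wnt, bone), and in the collagen, matricellular, Tgf-beta and bone lists the median and the enrichment test had opposite signs.

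In all, 4071 of the 5451 genes tested were called between Tw2_GM and Pax7_GM, 2654 of them (65.2%) higher in Tw2. With size factors, which moved the median of all genes from 0.34 by −0.84, 1393 were higher and 2940 lower (32.1% higher), and with quantile normalization, which moved it by −0.48, 1973 were higher and 2208 lower (47.2%). The libraries of 1 group lay wholly above those of the other for 4785 genes, where random labels on unselected genes would give 33.3%. The genes here were listed for differences between group means, and 2348 were at least 2-fold apart between these 2 groups. That share therefore does not measure chance here, nor do the shares for unselected genes given below. Genes poor in GC were higher in Tw2_GM, with medians of 1.83, 1.11, 0.37, −0.32 and −0.37 from the GC-poorest to the GC-richest of 5 equal groups (Spearman rho −0.69), and longer transcripts were higher too (rho 0.41). With that trend removed, which moved the median by 0.20, 3303 genes were higher and 784 lower (80.8%). Of the earlier calls, 2060 of 2554 genes called higher (80.7%) and 543 of 1362 called lower (39.9%) kept their call, and 82 and 327 were called the other way. A total of 1212 genes were higher and 513 lower as deposited, with each scaling and with the trend removed. In simulated counts with the spread of these libraries, where 200 of 5451 genes were changed, 36 of 195 calls in this comparison were of unchanged genes. Such a share depends on how many genes are changed, so it does not carry over to the 4071 calls.

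**Figure D2:**
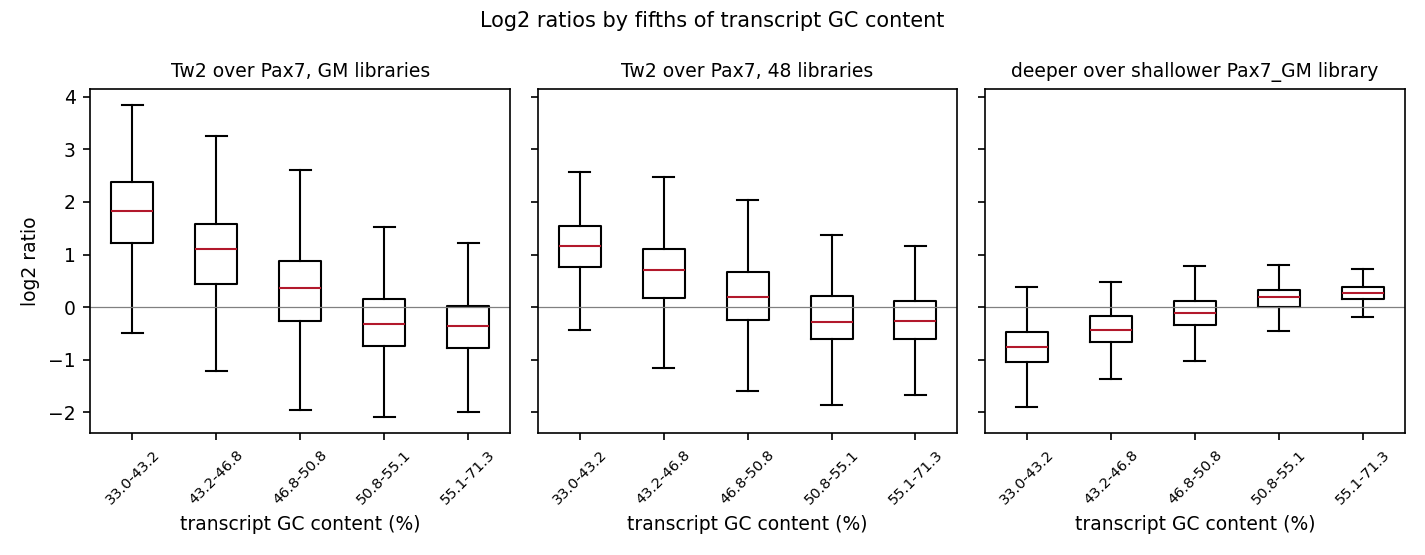
Log2 fold change of Tw2 over Pax7, and of the deeper over the shallower Pax7_GM library (rho 0.76), in 5 equal groups of genes by transcript GC content. In growth medium the medians ran from 1.83 in the GC-poorest group to −0.37 in the GC-richest, and in the 48 libraries from 1.17 to −0.27.

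In the 48 libraries, Tw2 cells had less of the imprinted RNAs Meg3 and Rian and more of the thyroid hormone deiodinase Dio2 and of Ptgs2 than Pax7 cells. Rian (chromosome 12, 109603940 to 109661716) was at 6.12 and 4.58 CPM in Tw2_48 and at 190 and 138 CPM in Pax7_48, a log2 fold change of −4.70 ± 0.25 (SE, 2 libraries per group; adjusted p = 2.92e-05). Its neighbour Meg3 (109541001 to 109571726) was at 2.62 and 2.13 CPM against 86.9 and 71.4 CPM (−4.57 ± 0.25, adjusted p = 2.92e-05). Dio2, which converts thyroxine to active thyroid hormone, was at 143 and 124 CPM in Tw2_48 against 10.8 and 13.0 CPM (3.39 ± 0.23, adjusted p = 7.77e-05).

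Other large differences were AW551984 (−4.80 ± 0.20), Arhgef5 (−4.21 ± 0.14), Syt13 (−3.68 ± 0.18), the inositol phosphate synthase Isyna1 (−3.58 ± 0.15) and Prrx1 (−3.37 ± 0.25). The dehydrogenase Dhrs4 was at −3.29 ± 0.14 and Tmem179 at −3.27 ± 0.20, and the adjusted p of these 7 ran from 8.07e-06 to 0.000107. Col1a2 was again lower, at 6.85 and 24.1 CPM in Tw2_48 and 270 and 246 CPM in Pax7_48 (−4.21 ± 0.44, adjusted p = 0.000338). Higher in Tw2_48 were Rab6b (3.56 ± 0.17), a GTPase of Golgi transport, Ptgs2 (3.33 ± 0.17), the RNA-binding protein Mex3b (2.79 ± 0.15), the cGMP-dependent kinase Prkg1 (2.76 ± 0.25) and the protocadherin Pcdhb19 (2.75 ± 0.17). Pgap1 (2.56 ± 0.22), which remodels lipid anchors, the p53 target Trp53inp1 (2.56 ± 0.32) and Pik3c2a (2.54 ± 0.49, adjusted p = 0.00322) were higher as well. Removing the trend left Pgap1 at 1.37, Trp53inp1 at 1.56, Pik3c2a at 1.39, Prkg1 at 1.82 and Pcdhb19 at 1.78, and Rab6b at 3.80 and Rian at −5.95. Pax7 was low in both groups, at 13.0 and 12.6 CPM in Tw2_48 and 9.58 and 9.95 CPM in Pax7_48 (0.35 ± 0.12, adjusted p = 0.0303), a difference that became −0.25 with size factors, 0.02 with quantile normalization and 0.63 with the trend removed (adjusted p = 0.00126). As deposited that call was lost when any 1 of the 48 libraries was left out, and also without 1 or the other Tw2_GM library (0.35 each), which is outside this comparison. It was lost as well with a pseudocount of 10 (0.20, adjusted p = 0.0775) and with unlisted genes counted (adjusted p = 0.122).

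Sarcomere genes were not called as a list, with 14 higher and 12 lower of 54 (13 and 10 adjusted over the list alone), a median of −0.01 and enrichment adjusted p = 0.283. The median was −0.67 with size factors, and 0.50 with the trend removed, where 30 were higher and 7 lower. They differed gene by gene. The fast myosin heavy chain Myh4 was at 15.7 and 15.2 CPM in Tw2_48 against 96.5 and 116 CPM (−2.70 ± 0.14) and Casq1 was at −1.61 ± 0.13 (−0.98 with the trend removed). The giant elastic protein titin, Ttn (1.55 ± 0.32), and the slow myosin heavy chain Myh7 (1.48 ± 0.14) were higher. Of 45 cell cycle genes 22 were lower and 3 higher (20 and 3 adjusted over the list alone), with a median of −0.39 and adjusted p = 7.14e-05, or adjusted p = 0.423 with an estimated correlation. Ccnd1, the D-type cyclin of G1, was at 13.69 and 15.01 CPM against 79.96 and 72.41 CPM (−2.33 ± 0.13), and the replication helicase subunits Mcm5 (−1.55 ± 0.21) and Mcm3 (−1.29 ± 0.15, and −0.85 with the trend removed) were lower. Quantile normalization gave this list adjusted p = 0.0557, and size factors gave a median of −0.92. With the trend removed 17 were lower and 4 higher (median −0.14). The enrichment test then gave adjusted p = 1.72e-06, and adjusted p = 0.633 with an estimated correlation.

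Oxidative phosphorylation genes were lower in 26 of 30 members and higher in 1 (26 and 1 over the list alone too), with a median of −0.70, adjusted p = 6.79e-09, and adjusted p = 0.424 with an estimated correlation. Among them were Atp5g1 (−1.08 ± 0.20), a subunit of the ATP synthase, Uqcrq (−0.94 ± 0.18, and −0.35 with the trend removed) of complex III and Ndufb5 (−0.84 ± 0.15) of complex I. With the GC and length trend removed 4 were lower and 5 higher, the median was 0.05 and adjusted p = 0.12. Wnt genes had 7 higher and 0 lower of 10, also adjusted over the list alone, with an enrichment adjusted p = 0.112. The ligand Wnt4 was at 97.3 and 87.2 CPM against 24.1 and 22.3 CPM (1.94 ± 0.17), and the transcription factors Tcf7 (1.16 ± 0.15) and Lef1 (0.96 ± 0.18) were higher too. Lef1 was not called with size factors (0.41, adjusted p = 0.0732). Elastic fibre and matricellular genes had 4 higher and 10 lower of 21 (7 and 10 adjusted over the list alone), with the growth factor Ctgf at −2.71 ± 0.14, and 5 and 5 of 18 with the trend removed.

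Among matrix inhibitors, Timp1, which blocks metalloproteinases, was at −3.05 ± 0.18, while Timp3 was at 1.58 ± 0.16. The chemokine Cxcl12 was at −2.40 ± 0.20, caveolin 1, Cav1, at −2.98 ± 0.18, the activin antagonist Fst at 2.21 ± 0.20 and the T-box factor Tbx18 at 2.20 ± 0.14. Xist was at 351 and 272 CPM in Tw2_48 and 70.9 and 66.6 CPM in Pax7_48 (2.15 ± 0.54, adjusted p = 0.00924, and 1.05 with the trend removed), a call lost without the shallower Pax7_48 (adjusted p = 0.0543) or the deeper Tw2_48 library (adjusted p = 0.0618). Besides the cell cycle and oxidative phosphorylation lists, the other 17 lists were not called (adjusted p from 0.112 to 0.985). Among the 19 lists tested, size factors changed the sign of 7 medians (commitment, basement membrane, axon guidance, Tgf-beta, Hox, pericyte, adipocyte). In the commitment, axon guidance and adipocyte lists the median and the enrichment test had opposite signs.

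Across the 48 libraries 3567 genes were called, 2362 (66.2%) higher in Tw2. With size factors, which moved the median of all genes from 0.27 by −0.63, 946 were higher and 2631 lower (26.4% higher), and with quantile normalization, which moved it by −0.29, 1606 were higher and 1715 lower (48.4%). With the GC and length trend removed 2465 were higher and 695 lower (78.0%). The groups did not overlap for 4883 genes (33.3% for unselected genes). The trend with GC content was present here too (rho −0.62 with GC, 0.42 with length, medians from GC-poor to GC-rich genes 1.17, 0.71, 0.20, −0.29 and −0.27). The count was 2259 without the shallower Pax7_48 library and 2151 without the deeper Tw2_48 library.

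**Figure D3:**
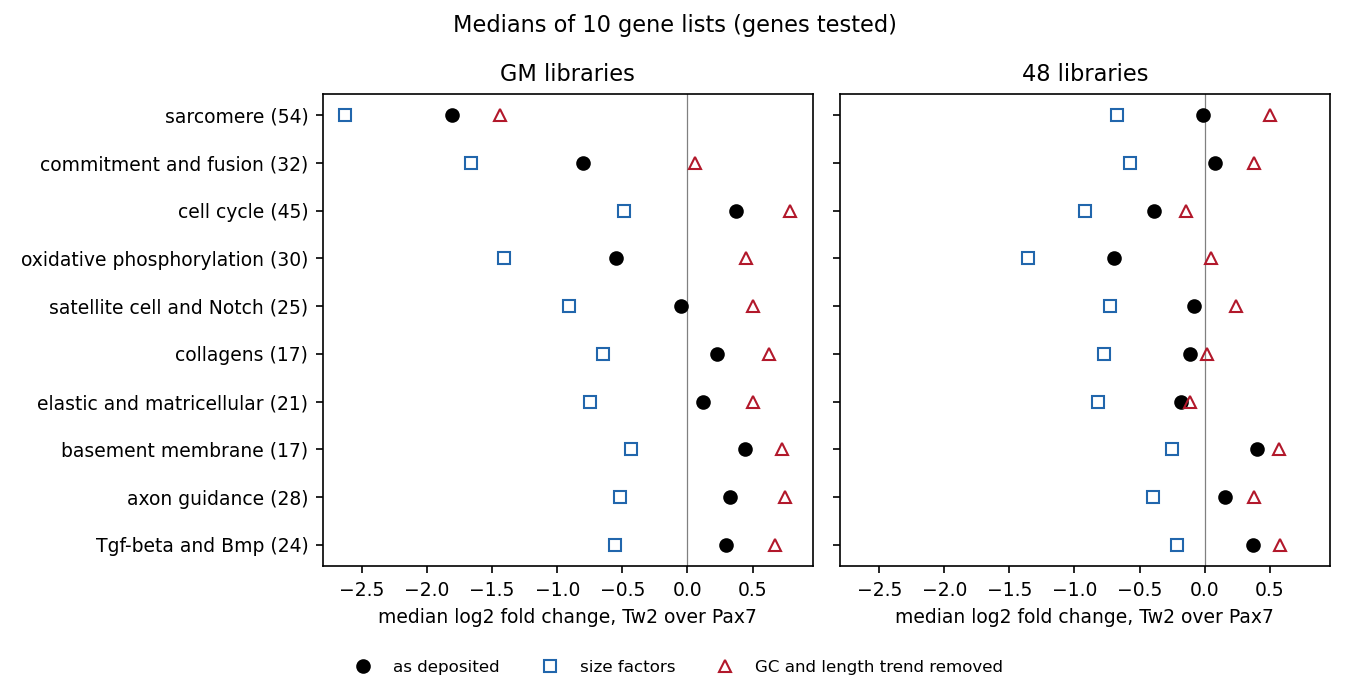
Median log2 fold change of Tw2 over Pax7 for 10 gene lists, as deposited, with size factors and with the GC and length trend removed. The sarcomere median in growth medium was −1.81, −2.63 and −1.44 under these.

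Over both cultures together, Tw2 cells had less Col1a2, Meg3, Rian and Prrx1 and more Rab6b and Ptgs2 than Pax7 cells. Col1a2 was at −5.36 ± 0.31 (SE, 4 libraries per lineage; adjusted p = 8.51e-06), and Rian at −3.87 ± 0.18 (adjusted p = 3.73e-06). Meg3 was at −3.60 ± 0.17 (adjusted p = 4.03e-06) and Prrx1, a homeobox factor of limb mesenchyme, at −3.19 ± 0.18 (adjusted p = 6.98e-06). Arhgef5 was at −4.14 ± 0.10, AW551984 at −4.02 ± 0.14, Syt13 at −3.96 ± 0.12, and Dhrs4 at −3.16 ± 0.10. The proton pump subunit Atp6v0e2 was at −2.94 ± 0.09 and Pcbd1, an enzyme of tetrahydrobiopterin recycling, at −2.85 ± 0.13. Ptgs2 stood at 3.50 ± 0.12 (adjusted p = 1.62e-06) and Rab6b at 2.94 ± 0.12 (adjusted p = 2.74e-06).

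Dock11 (3.12 ± 0.22), Pik3c2a (3.08 ± 0.35), the chaperone Hsp90aa1 (2.85 ± 0.30), Far1 (2.83 ± 0.34) and the RNA helicase Ddx3x (2.82 ± 0.29) were higher in Tw2. So were the ubiquitin ligase Dzip3 (2.78 ± 0.18), Ipo7 (2.77 ± 0.24), Flrt2 (2.75 ± 0.15) and the Rab27 effector Sytl5 (2.74 ± 0.21). Itga6 (2.13 ± 0.12), Eng (2.20 ± 0.13), Tgfbr1 (2.56 ± 0.22), Sema3a (2.40 ± 0.23) and the zinc finger factor Klf4 (1.61 ± 0.10) were higher too, and Emilin1 was lower (−2.35 ± 0.14). Removal of the trend left Dock11 at 1.97, Pik3c2a at 1.65, Ddx3x at 1.78, Dzip3 at 1.34 and Ipo7 at 1.67, and made Far1 and Flrt2 smaller as well. Tgfbr1 was then at 1.42 and Sema3a at 1.23, and Sytl5 at 2.69. Ddx3x and Sytl5 are also on the X chromosome. Pax7 was at 0.15 ± 0.08 (adjusted p = 0.126), at −0.58 with size factors, −0.29 with quantile normalization, and 0.57 with the trend removed (adjusted p = 0.000145).

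Sarcomere genes were lower in 42 of 54 members and higher in 5 (the same over the list alone), with a median of −0.93, adjusted p = 4.2e-11, and adjusted p = 0.472 with an estimated correlation. There were 30 lower and 14 higher with the trend removed (median −0.48). Casq1 (−2.86 ± 0.09), Mb (−2.73 ± 0.15, and −1.67 with the trend removed), Myh4 (−2.60 ± 0.10) and Myl4 (−2.26 ± 0.12) led it. Commitment and fusion genes were lower in 18 of 32 and higher in 10 (the same over the list alone), with a median of −0.43, adjusted p = 0.0206, and adjusted p = 0.472 with an estimated correlation. Mef2c was at −1.75 ± 0.18 and its relative Mef2a at 1.87 ± 0.18 (−2.94 and 0.86 with the trend removed). This call was not made with size factors (adjusted p = 0.0971), quantile normalization (adjusted p = 0.1) or the trend removed (adjusted p = 0.264, with 16 higher and 8 lower). Oxidative phosphorylation genes were lower in 28 of 30 and higher in 1 (the same over the list alone), with a median of −0.62. With the trend removed 4 were lower and 17 higher, and the median was 0.27. Cox6a2 was at −1.73 ± 0.13 (−0.59 with the trend removed) and Uqcrq at −0.82 ± 0.13 (−0.11 with the trend removed, adjusted p = 0.214). The list had adjusted p = 2.39e-08, adjusted p = 0.472 with an estimated correlation, and adjusted p = 0.642 with the trend removed. Cell cycle genes had 15 higher and 14 lower of 45 as deposited (median −0.03), and 25 and 7 with the trend removed (median 0.31), while size factors gave a median of −0.73.

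For the lineages over both cultures, 4298 genes were called, 2713 (63.1%) higher in Tw2. Size factors moved the median of all genes from 0.27 by −0.72 and gave 1427 higher and 3063 lower (31.8% higher), and quantile normalization moved it by −0.37 and gave 2050 higher and 2349 lower (46.6%). Removal of the trend gave 3316 higher and 803 lower (80.5%). All 4 libraries of 1 lineage lay above those of the other for 1586 genes (2.9% for unselected genes). Between the 2 cultures, 2015 genes were higher in Tw2 in both, where 1150 would be if the calls were independent. A further 799 were lower in both (313 if independent) and 179 were called in opposite directions (r 0.78 between the fold changes). With the trend removed 2051 were higher in both (1552 if independent), 369 lower in both (104 if independent) and 277 opposite (r 0.61). Outside the sarcomere, commitment and oxidative phosphorylation lists the 16 lists had adjusted p from 0.119 to 0.847. With size factors 6 medians of the 19 lists tested changed sign (collagens, basement membrane, axon guidance, Tgf-beta, Wnt, Hox), and the collagen and Hox medians had the sign opposite to the enrichment test.

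From growth medium to the 48 libraries, Pax7 cells lost cell cycle transcripts and gained those of the contractile apparatus. Cdkn1c, an inhibitor of cyclin-dependent kinases, rose from 17.6 and 11.2 CPM to 1141 and 1291 CPM, a log2 fold change of 6.33 ± 0.21 (SE, 2 libraries per group; adjusted p = 1.99e-07). Ckm, the creatine kinase of muscle, rose from 13.55 and 11.96 CPM to 419 and 591 CPM (5.18 ± 0.17, adjusted p = 1.99e-07). Pax7 (chromosome 4, 139737062 to 139833528) fell from 117 and 112 CPM to 9.58 and 9.95 CPM (−3.42 ± 0.12, adjusted p = 2.03e-07).

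Ctrb1, which encodes the protease chymotrypsinogen, rose by 5.93 ± 0.15, the microfibril protein Mfap4 by 5.25 ± 0.16 and Pgm5, a phosphoglucomutase relative found at adhesion sites, by 5.20 ± 0.19. The hormone gene Sct fell (−5.97 ± 0.26), as did the acyl-CoA synthetase Acsbg1 (−5.85 ± 0.16), the neuropeptide receptor Adcyap1r1 (−5.76 ± 0.17) and Selp (−5.59 ± 0.22). In the authors' deposited table, the Pax7 means of Acta1 went from 1223 to 11091 CPM, those of Actc1, the cardiac actin, from 664 to 12605 CPM, and those of Myh3 from 388 to 8729 CPM.

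All 45 cell cycle genes fell (45 over the list alone), with a median of −4.13, adjusted p = 8.07e-15, and adjusted p = 0.162 with an estimated correlation. Kif2c (−5.17 ± 0.18), a microtubule depolymerase, Cenpa (−4.99 ± 0.17), the centromeric histone, Cdc20 (−4.94 ± 0.13), an activator of the anaphase-promoting complex, and the kinase Aurkb (−4.86 ± 0.12) fell most. Sarcomere genes rose in 51 of 54 members and fell in 2 (52 and 2 over the list alone), with a median of 3.14, adjusted p = 8.07e-15, and adjusted p = 0.196 with an estimated correlation. Atp2a1 (4.77 ± 0.22), the calcium pump of the sarcoplasmic reticulum, the troponin Tnnc2 (4.69 ± 0.18) and the myosin-binding protein Mybph (4.50 ± 0.17) rose with Ckm. Commitment and fusion genes rose in 26 of 32 and fell in 5 (the same over the list alone), with a median of 1.88, adjusted p = 1.4e-05, and adjusted p = 0.162 with an estimated correlation. Unc45b (4.08 ± 0.18) and Klhl40 (3.99 ± 0.17) rose among them. Tmem8c, the gene of the fusion protein myomaker, rose from 233 and 199 CPM to 3384 and 3557 CPM.

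All 30 oxidative phosphorylation genes rose, 30 over the list alone, with a median of 0.85, adjusted p = 2.15e-05, and adjusted p = 0.517 with an estimated correlation. Cox8b rose by 4.40 ± 0.24 and Cox6a2 by 3.35 ± 0.18. Elastic fibre and matricellular genes fell in 16 of 21 and rose in 3 (the same over the list alone), among them tenascin C, Tnc (−4.45 ± 0.20), and fibronectin, Fn1 (−3.05 ± 0.13). The median of that list was −1.91 (adjusted p = 0.00626, and adjusted p = 0.221 with an estimated correlation). Cytokines and chemokines fell in 5 of 6 and rose in 1 (the same over the list alone), with Cxcl12 at −4.53 ± 0.20 and the macrophage growth factor Csf1 at −3.44 ± 0.14. Their median was −3.15 (adjusted p = 0.0457, adjusted p = 0.221 with an estimated correlation, and adjusted p = 0.0607 with the GC and length trend removed). The call was also lost without the deeper Pax7_GM library (adjusted p = 0.0748). Id3 (−5.33 ± 0.23) and Id1 (−4.17 ± 0.21), inhibitors of basic helix-loop-helix factors, also fell, as did Nr4a2 (−4.58 ± 0.21), Fosl1 (−4.55 ± 0.18) and Myc (−3.40 ± 0.15), while Wnt4 rose (3.41 ± 0.17).

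Between Pax7_GM and Pax7_48, 4319 genes changed, 2112 up and 2207 down (48.9% up), and the groups did not overlap for 4634 genes (33.3% for unselected genes). Size factors moved the median of all genes from 0.01 by 0.24 (54.6% up) and quantile normalization by 0.13 (51.9% up). The share was 44.2% without the deeper and 54.8% without the shallower Pax7_GM library. The other 13 lists were not called (adjusted p from 0.0611 to 0.893), and among the lists tested the medians of Tgf-beta and Wnt changed sign with size factors.

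In Tw2 cells, contractile genes rose and cell cycle genes fell from growth medium to the 48 libraries. Tnnc2, the fast troponin C, rose from 11.6 and 8.59 CPM to 2258 and 2430 CPM (log2 fold change 7.74 ± 0.18 SE, 2 libraries per group; adjusted p = 1.45e-08). Cdkn1c rose from 6.49 and 5.22 CPM to 1431 and 1416 CPM (7.71 ± 0.21, adjusted p = 1.88e-08), and Pgm5 (7.70 ± 0.19), Ablim3 (7.57 ± 0.17) and the perinatal myosin heavy chain Myh8 (7.57 ± 0.18) rose too. Cxcl12 fell from 486 and 427 CPM to 1.89 and 3.40 CPM (−7.00 ± 0.20, adjusted p = 2.24e-08). Pax7 fell from 113 and 109 CPM to 13.0 and 12.6 CPM (−3.02 ± 0.12, adjusted p = 8.71e-08).

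Selp (−7.58 ± 0.22), Top2a (−6.66 ± 0.33) and Mki67 (−6.61 ± 0.47) fell as well. In the authors' deposited table, the Tw2 means of Acta1 went from 180 to 12723 CPM, those of Actc1 from 131 to 20911 CPM, and those of Myh3 from 91.1 to 20577 CPM. Means of Cfl2, the cofilin of muscle, were 195 and 1102 CPM in the authors' deposited table, and those of the imprinted RNA H19 were 10245 and 35032 CPM.

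Sarcomere genes rose in 52 of 54 members and fell in 2 (the same over the list alone), with a median of 5.27, adjusted p = 1.19e-18, and adjusted p = 0.135 with an estimated correlation. Myl4 (7.53 ± 0.18) and Ckm (7.42 ± 0.17) rose with Tnnc2 and Myh8. All 45 cell cycle genes fell (45 over the list alone), among them Ccnd1 (−6.33 ± 0.13) and Anln (−6.22 ± 0.22), with a median of −5.16, adjusted p = 2.35e-12, and adjusted p = 0.135 with an estimated correlation. Commitment and fusion genes rose in 26 of 32 and fell in 6 (the same over the list alone), with Unc45b at 6.77 ± 0.18, Gm7325 at 6.25 ± 0.21 and Klhl41, a stabilizer of thin filaments, at 6.18 ± 0.14. The median was 2.35 (adjusted p = 2.04e-06, and adjusted p = 0.135 with an estimated correlation).

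Oxidative phosphorylation genes rose in 27 of 30 (27 over the list alone), with Cox8b at 5.87 ± 0.24, Cox6a2 at 5.51 ± 0.18 and a median of 0.72. Its adjusted p = 6.16e-05 became adjusted p = 0.508 with an estimated correlation and adjusted p = 0.0726 with the GC and length trend removed, where 14 rose and 5 fell. All 6 cytokines and chemokines fell (6 over the list alone), with a median of −2.67, adjusted p = 0.0356, adjusted p = 0.267 with an estimated correlation, and adjusted p = 0.069 with the trend removed. The call was lost as well when 1 or the other Pax7_GM library was left out (adjusted p = 0.0538 each). Csf1 was at −4.85 ± 0.14. Elastic fibre and matricellular genes fell in 16 of 21 and rose in 4 (the same over the list alone), with adjusted p = 0.0682 for the list. Tnc fell by 5.10 ± 0.20 and osteopontin, Spp1, by 5.28 ± 0.28, while Mfap4 rose by 6.67 ± 0.16. The hepatocyte growth factor receptor Met (−4.80 ± 0.18), the adhesion molecule Vcam1 (−4.33 ± 0.18), Fosl1 (−6.03 ± 0.18) and Id3 (−6.41 ± 0.23) fell. Wnt4 (5.17 ± 0.17), the Bmp antagonist Chrd (4.85 ± 0.18) and the smooth muscle actin Acta2 (3.94 ± 0.13) rose.

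Between Tw2_GM and Tw2_48, 4586 genes changed, 1922 up (41.9%) and 2664 down, with no overlap of the groups for 5177 genes (33.3% for unselected genes). The median of all genes was −0.50. Size factors moved it by 0.45 and gave 2188 up and 2218 down (49.7% up), quantile normalization moved it by 0.24 and gave 2071 and 2492 (45.4%), and removal of the trend moved it by 0.22 and gave 1883 and 2550 (42.5%). Since a gene at least 2-fold apart in Tw2_48 and Tw2_GM was listed for that reason, these shares describe the selection as well as the cells. The other 14 lists were not called (adjusted p from 0.0682 to 0.933), and the Wnt median had the sign opposite to its enrichment test. The changes of the 2 lineages went together, with 1811 genes up in both (745 if independent), 2147 down in both (1079 if independent) and 23 in opposite directions (r 0.95).

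**Figure D4:**
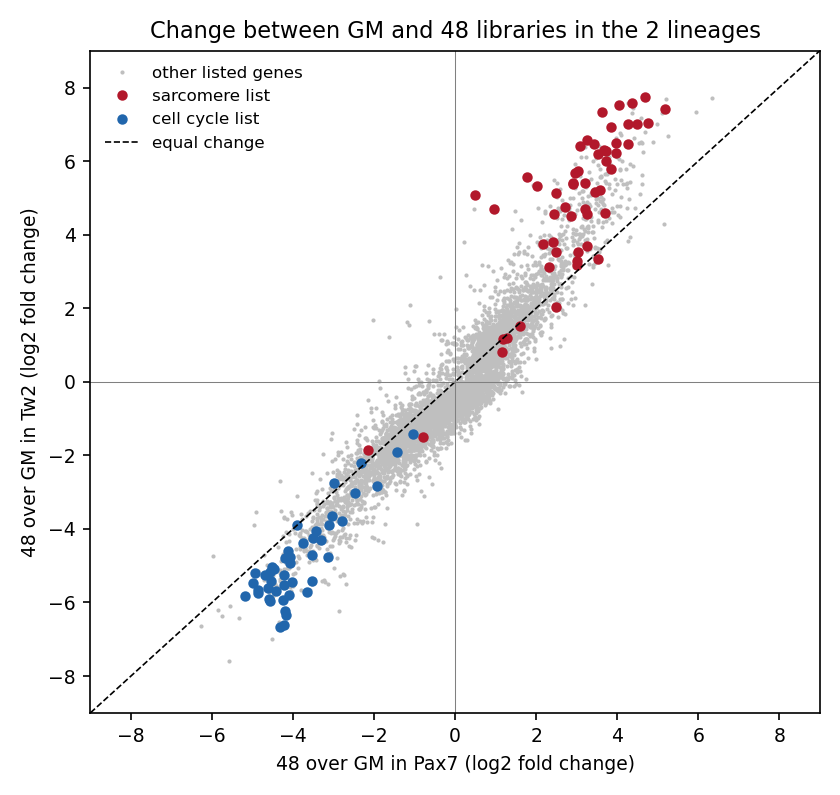
Log2 fold change from growth medium to the 48 libraries in Pax7 and in Tw2 cells. The 2 correlated at 0.95, and of the named genes Mb differed most, by 4.57.

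The change from growth medium to the 48 libraries differed between the lineages most for contractile genes, which rose more in Tw2 cells from a lower start. Mb rose in Tw2 cells from 6.08 and 4.25 CPM to 196 and 211 CPM, and in Pax7 cells it went from 233 and 166 CPM to 301 and 256 CPM. The difference in log2 change was 4.57 ± 0.30 (SE, 8 libraries; adjusted p = 0.000142). Csrp3, a LIM protein of the Z-disc, differed by 3.80 ± 0.19, Myh7 by 3.74 ± 0.19, Igfn1 by 4.24 ± 0.22 and Ltbp2 by 3.73 ± 0.20, each with adjusted p = 6.95e-05. Myog, the transcription factor myogenin, went from 110 and 89.1 CPM to 3697 and 3859 CPM in Tw2 cells and from 439 and 351 CPM to 2491 and 2247 CPM in Pax7 cells (2.65 ± 0.23, adjusted p = 0.000325).

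Differences in the other direction were those of Dynap (−3.38 ± 0.25, adjusted p = 0.00018) and Cav1 (−2.93 ± 0.26, adjusted p = 0.000333). Timp1 (−2.57 ± 0.26, adjusted p = 0.000587) and the chromatin factor Atad2 (−2.49 ± 0.52, adjusted p = 0.0145) went the same way. Timp1 went from 281 and 347 CPM to 12.8 and 15.8 CPM in Tw2 cells and from 498 and 381 CPM to 123 and 127 CPM in Pax7 cells. Tenm4, a teneurin, was at 3.59 ± 0.32, Wnt9a at 2.14 ± 0.18, Cxcl12 at −2.47 ± 0.28 and Pax7 at 0.40 ± 0.17 (adjusted p = 0.13, and 0.506 with the trend removed).

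Of the 54 sarcomere genes, 42 changed more upward in Tw2 cells and 0 less, also adjusted over the list alone, with a median difference of 2.22, adjusted p = 4.97e-31, and adjusted p = 0.0991 with an estimated correlation. Commitment and fusion genes did so in 16 of 32, against 1 (18 and 2 over the list alone), among them Unc45b (2.69 ± 0.25) and Klhl41 (2.67 ± 0.19). Their median was 0.69, adjusted p = 2.84e-07, and adjusted p = 0.0991 with an estimated correlation. That median was 0.89 with size factors, 1.24 with quantile normalization and 0.46 with the trend removed. Cell cycle genes changed more downward in Tw2 cells in 24 of 45 members and more upward in 0 (34 and 0 over the list alone), with a median of −0.86 (−0.47 with size factors and −0.45 with quantile normalization), adjusted p = 1.68e-08, and adjusted p = 0.248 with an estimated correlation. Ccnd1 was at −2.15 ± 0.19, Top2a at −2.33 ± 0.47 and Mki67 at −2.39 ± 0.66 (adjusted p = 0.0411, and adjusted p = 0.0761 with size factors). The call of Mki67, at 0.658 and 1.18 CPM in Pax7_48, was lost without any 1 Pax7_48, Tw2_48 or Tw2_GM library (−2.06 to −2.72). It was also lost with quantile normalization (−1.77, adjusted p = 0.0808), a pseudocount of 0.1 (adjusted p = 0.115) and unlisted genes counted (adjusted p = 0.166). That of Top2a was lost without the deeper Pax7_48 (−2.13), the shallower Tw2_48 or the deeper Tw2_GM library (−2.21 each). That of Atad2 was lost without the shallower Pax7_48 or Tw2_48 (−2.34 each) or the deeper Tw2_GM library (−2.32). Of 5 adipocyte markers 2 were called upward and 0 downward (3 and 0 over the list alone), Car3 at 2.67 ± 0.24 and Scd1 at 2.21 ± 0.36. Their median was 1.67 (0.69 with quantile normalization), adjusted p = 0.00819, and adjusted p = 0.352 with an estimated correlation.

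In total, 1021 genes differed in their change between the lineages, 530 upward in Tw2 (51.9%) and 491 downward. Size factors moved the median of all genes from −0.22 by 0.22 and gave 656 and 223 of 879 (74.6% upward). Quantile normalization moved it by 0.16 and gave 690 and 458 of 1148 (60.1%). With the GC and length trend removed the counts were 593 and 1114 of 1707 (34.7%) (rho with GC 0.47). A pseudocount of 0.1 gave 525 and 412 of 937 (56.0%), and a pseudocount of 10 gave 554 and 855 of 1409 (39.3%). Single libraries moved both the count and its balance. Without the shallower Pax7_GM library 3153 genes were called (30.5% upward), and without the deeper one 1727 (41.9%). Without any 1 of the other 6 libraries 449 to 510 were called, with 63.7 to 71.9% upward. The other 15 lists were not called (adjusted p from 0.0912 to 0.997), although oxidative phosphorylation was with the trend removed (adjusted p = 0.0333, 2 upward and 15 downward, and adjusted p = 0.742 with an estimated correlation). With size factors 5 medians changed sign (satellite cell, fibro-adipogenic, Tgf-beta, immediate early, oxidative phosphorylation), and the fibro-adipogenic, basement membrane and Tgf-beta medians had the sign opposite to the enrichment test.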

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

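The tests on the lower calls, on the trend between the Pax7_GM libraries, on the implied share of cells and on the remaining imprinted genes were chosen after the results they test were seen, as was the comparison of the cell cycle median with that of all genes; the other tests here were fixed before their values were computed.

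The change from growth medium to 48 differed between the lineages by a test of the difference itself for 1021 genes, and this is what marked the following for a closer look. Upward in Tw2 were Mb (4.57), Igfn1 (4.24), Csrp3 (3.80), Myh7 (3.74) and Ltbp2 (3.73). Downward in Tw2 were Dynap (−3.38), Cav1 (−2.93), Timp1 (−2.57) and Atad2 (−2.49).

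Lineage differences in growth medium followed transcript GC content and length, which may be a property of the libraries or of the cells. The fitted trend was not the whole cause of the calls. With it removed 66.5% of the genes called kept their call, where 46.3% would if the calls before and after were unrelated. Of those called lower in Tw2 only 39.9% did (14.9% if unrelated), which leaves open how many of these are differences between the lineages. The removal kept each library's mean level, which favours calls higher in Tw2, and both sets of calls came from the same libraries. The calls kept are therefore not shown to be differences between the lineages. A library trend without lineage was present in growth medium, where the ratio of the 2 Pax7_GM libraries had a rho of 0.76 with GC content. Removal of the trend brought the SD of their log2 ratio from 0.50 to 0.30 (0.15 to 0.18 in the other groups). Library effects beyond the fitted trend are thus not excluded. The ratios of the deeper to the shallower library had weaker rhos of the other sign in Tw2_GM and Tw2_48 (−0.36 each) and in Pax7_48 (−0.29), so no pair at 48 had a trend as strong as that between the lineages there (−0.62). Cell cycle genes had a median of 0.37 (95% interval 0.20 to 0.48), and 0.79 with the trend removed. That rise decides nothing about the trend, since the median of all genes was 0.34, within that interval, and rose to 0.53 too. Their fold changes did follow GC content within the list (rho −0.74, and 0.10 with the trend removed). Against the other genes the list had adjusted p = 0.37, and 0.168 with the trend removed, so whether cell cycle genes were higher in Tw2_GM stays open.

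Sarcomere genes were lower in Tw2_GM than in Pax7_GM, and neither the fitted trend nor 1 of the Pax7_GM libraries alone accounts for that. The median was −1.44 (95% interval −1.95 to −0.93) with the trend removed, and −1.81 without the Pax7_GM library that left the smaller difference. A share of Pax7_GM cells already in the state of Pax7_48 could give the same difference. That share was computed from mean CPM, with the trend left in, as if all other Pax7_GM cells were at the Tw2_GM level. It thus presumes that those cells do not differ between the lineages. The share implied by each of 54 genes had a median of 7.1% and quartiles of 4.1 and 11.7%, and 63.0% of the genes lay within 2-fold of the median, which leaves this explanation open for the list. The shares ran from −14.1 to 73.5%, and that of Mb was 71.0%, so a share near the median does not give the level of Mb.

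Meg3 and Rian, neighbours in an imprinted region of chromosome 12, were lower in Tw2 in both cultures. GC content and length do not account for this, since the smaller difference of the 2 was −3.79 over both cultures with the trend removed. Whether imprinted genes as a class differ by parental copy stays open: without these 2 genes, the exact permutation p for paternally against maternally expressed genes was 0.695.

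Of the splits of the libraries into 4 and 4 that can be fitted beside the culture, 1 of 34, the real one, called 3791 genes, and the highest of the other splits called 0. With the GC and length trend removed the real split called 3422 genes and the highest of the others 26. The genes had been listed for a difference between group means, which favours the real split, and 18 splits have 2 libraries of each culture on either side, too few for a share under 0.05.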

How the results depend on the processing

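Removal of the GC and length trend, unlisted genes counted as p of 1, a separate spread per group, and the list tests under scaling, trend removal and left-out libraries were chosen after seeing the data. The other alternatives were fixed before the data were examined. Where a value changed and nothing else is said, the cause was not tested.

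Counts of called genes stayed within 1.5 times under both scalings, the intensity trend, both pseudocounts, the filter at 10 CPM, the compared groups alone and a separate spread per group. Their balance did not always hold. For the difference of changes the share upward went from 51.9% to 56.0% with a pseudocount of 0.1 and to 39.3% with a pseudocount of 10. An added minimum of 1 on the absolute log2 fold change left 2353 genes in GM, 1485 at 48, 1827 over both, 2856 for the change in Pax7 cells and 645 for the difference of changes, by the construction of that limit. The difference of changes had 1707 genes with the trend removed and 476 with unlisted genes counted. With single libraries left out it ranged from 449 to 3153, highest without the shallower Pax7_GM library, with 30.5 to 71.9% upward, and the comparison at 48 ranged from 2151 to 4217. A group with 1 library left was assumed to vary like the others.

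Pax7 in GM, at −0.05, went to −0.91 with size factors and −0.60 with quantile normalization, each called, and turned to 0.50 with the trend removed. It turned at 48 with size factors (−0.25), and over both with size factors (−0.58) and quantile normalization (−0.29), while removal of the trend gave 0.63 at 48 and a call at 0.57 over both. Igf2 over both turned with size factors (−0.72) and was called at 0.58 with the trend removed. Sgce over both turned with size factors (−0.44), quantile normalization (−0.15) and the trend removed (−0.93), and Cdkn1c with the trend removed (0.44). Over all genes, 2810 of the 4071 calls in GM kept direction and call with size factors and 3287 with quantile normalization. With the trend removed 2603 of 3916 did. At 48, 2151 of 3567 did with size factors and 2738 with quantile normalization. Named genes were mostly picked for their large changes, which favours keeping a call. Of 222 results for named genes, 212 kept direction and call with size factors, 215 with quantile normalization and 212 of 218 with the trend removed. With libraries left out 1746 results did and 29 lost their call, among them Atad2, Mki67 and Top2a in the difference of changes, Cdkn1c and Sgce over both, and Xist at 48 (adjusted p = 0.0543 without the shallower Pax7_48 library).

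For lists, fry gave the opposite direction to camera in GM for Tgf-beta (adjusted p = 0.0162), collagens (0.0466) and cytokines (0.00347), at 48 for commitment (0.0297) and over both for Hox (0.00599), and camera with the trend removed did so for oxidative phosphorylation in GM (0.828). All 23 list calls were lost with an estimated correlation, and fry called 60 lists that camera did not. These tests ask different questions, since fry compares the genes of a list with no change and camera compares them with the other listed genes. Differences between fry and camera, or between the sign of a list median and camera, are therefore not effects of processing alone.

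The filter at a mean of 1 CPM removed no gene, so its absence changed nothing. The compared groups alone gave no separate value over both cultures or for the difference of changes. No paired analysis was possible because the columns carry no replicate numbers, and the replicate block was not run.

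The simulated counts had no trend with GC content, so the rates in the real libraries may differ. The share of false calls also depends on how many genes are changed. Far more of the real genes were called (74.7% in GM), so that share does not carry over to them. Where 200 of 5451 simulated genes were changed, 50.7% of 1.5-fold, 88.1% of 2-fold and 66 of 66 4-fold changes were found in GM, with 36 of 195 calls false. At 48 these were 32.8, 95.5 and 95.5% (4 of 153 false), and for the difference of changes 11.9, 56.7 and 95.5% (1 of 110 false).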

Other observations

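The imprinted genes here were gathered after Meg3, Rian and Peg3 had been seen, and the permutation test across them was chosen then too.

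Several paternally expressed genes were higher in Tw2 than in Pax7 cells over both cultures. Plagl1, a zinc finger factor, was at 2.54 ± 0.16 (adjusted p = 1.17e-05), at 1576 and 1430 CPM in Tw2_GM and 134 and 227 CPM in Pax7_GM. Impact was at 2.14 ± 0.24, the retrotransposon-derived Peg10 at 1.90 ± 0.11, Mest at 1.68 ± 0.10 and the Notch ligand relative Dlk1 at 1.06 ± 0.20 (0.40 with size factors, adjusted p = 0.11). Ndn, which encodes necdin and is also paternally expressed, was lower (−2.61 ± 0.11, adjusted p = 3.14e-06), and Igf2, the insulin-like growth factor, was at 0.05 ± 0.09 (adjusted p = 0.616), or −0.72 with size factors (adjusted p = 7.92e-05) and 0.58 with the GC and length trend removed (adjusted p = 0.000753). Of maternally expressed genes, Igf2r, a receptor that clears that growth factor, was at −0.76 ± 0.10 and Zim1 at 2.35 ± 0.26. With the trend removed Zim1 was at 1.26 and Impact at 1.33. The maternally expressed Cdkn1c turned from −0.46 to 0.44 and the paternally expressed Sgce from 0.27 to −0.93, and each of these 2 calls, as deposited, was lost without the shallower Pax7_48 library (adjusted p = 0.0725 and 0.145). Both were also lost without the deeper Tw2_48 (0.055 and 0.0971), the shallower Tw2_48 (0.0567 and 0.104) or the shallower Tw2_GM library (0.0765 and 0.0587), and that of Sgce without the deeper Tw2_GM library (0.136).

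A hypothesis was that the lineages differ in paternally against maternally expressed genes. Between 12 paternally and 5 maternally expressed genes the mean log2 fold change differed by 2.16 as deposited (exact permutation p = 0.0343, 6188 arrangements) and by 2.35 with the GC and length trend removed (exact permutation p = 0.0263). Without Meg3 and Rian the difference was 0.36 (exact permutation p = 0.695, 455 arrangements), and without Peg3 as well, the other gene that prompted the test, it was 0.28 (exact permutation p = 0.78, 364 arrangements). The data do not show a difference beyond these genes.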
